A study of Mus musculus with 8 samples.

How the data were processed

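The deposited table holds read counts per gene for 8 libraries of sorted mouse neutrophils, in 4 groups of 2. Per the labels' protocols, total RNA was extracted with the Zymo Quick-RNA Microprep kit, and libraries were made with an Illumina stranded kit for total RNA (Ribo-Zero Plus), which removes ribosomal RNA and keeps transcripts without a poly(A) tail. Per the submitters' processing notes, the authors used FastQC, cutadapt, STAR, featureCounts and DESeq2 with the mouse build mm10. Tool versions, the strand setting of the counting and the order of the steps were not given in the sources used here. The deposited counts are whole numbers that were not normalized. All 55450 gene IDs of the table, with their versions and names, were found in GENCODE release M21, from which coordinates were taken. Every row named a gene, and 29244 genes had a count in at least 1 library. A read that falls on exons of overlapping genes, on an antisense partner or on a near-identical copy could be split or lost in the authors' counting, so such genes are named as uncertain.

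Total counts ran from 9598959 to 22615813 per library. A gene with 0 counts in a library allows up to 3 counts there, which on the TMM-scaled library sizes used for CPM is 0.0915 to 0.419 CPM. This floor covers counting error only, and the reads carry no molecular identifiers. Bootstrap intervals of list medians cover the spread between genes of a list. The labels name separate samples but not separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. No replicate pair held identical values. A chi-square test of the counts of each pair gave 14.5 to 77.4 per degree of freedom, above counting noise, as separate preparations of the same cells would also be. Each library was treated as a sample because the labels name it as one.

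Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 15975 genes, and libraries were scaled by TMM factors. A model of 4 group means was fitted to all 8 libraries with robust dispersions (common biological coefficient of variation 0.19, 4 residual degrees of freedom). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was run for 5 comparisons, namely CD71+ against CD71− in the tumour, the same in culture, the difference between these effects, and tumour against culture within each sort fraction. A gene passed at an adjusted p under 0.05. CPM values were computed by edgeR on the TMM-scaled library sizes. For genes with 0 counts in every library of a group, the fold is given as a bound, computed against 3 counts per library. Where a group held 1 to 3 counts, levels are given without a fold.

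There were 28 gene lists, written from textbook knowledge. Maturation lists were early neutrophil and primary granule, mature neutrophil, and secondary granule genes. Lists of other cells held markers of macrophages and monocytes, microglia, dendritic cells, lymphocytes, endothelial and stromal cells, glioma and neural cells, eosinophils with basophils and mast cells, megakaryocytes and platelets, and erythroid cells. The remaining lists were hypoxia response, glycolysis and lactate, histone acylation writers and erasers, suppressive neutrophil markers, inflammatory cytokines and chemokines, type I interferon response, antigen presentation, NADPH oxidase and phagocytosis, lipid uptake and storage, iron uptake and storage, Myc and ribosome biogenesis, cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, amino acid stress and unfolded protein response, and immediate early and heat shock genes. The lists of mitochondrially encoded transcripts and of immediate early and heat shock genes were written as checks of sample quality. Of all members, 1 erythroid gene was not found in the table. Each list with at least 5 tested members, 27 of the 28, was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. Adjustment was over the 27 lists of a comparison. Counts of members that passed are given over all genes tested and adjusted over the list alone.

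The text names Tfrc, the gene of the sort marker, and 12 genes tied to the study's question (Arg1, Vegfa, Cd274, Slc2a1, Ldha, Hif1a, Ep300, Il1b, Cd14, Olr1, Tnfrsf10b and Ly6g). It also names the 8 largest rises and 8 largest falls of each comparison (5 of each sign for the difference) among genes that passed, had a mean of at least 5 CPM and did not overlap between the groups, and up to 2 rises and 2 falls from each list. For the difference, genes could overlap between the groups. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except for scaling on the mature neutrophil list and the tests of technical explanations, which were chosen after seeing the data. The alternatives were DESeq2 size factors and total counts in place of TMM, no filter and a filter of 5 CPM in 2 libraries, removal of mitochondrial, ribosomal RNA and haemoglobin genes before scaling, each library left out in turn, a replicate block, only the 4 libraries compared, a 2-fold minimum, DESeq2 1.42.0, limma-voom and edgeR's legacy dispersions.

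The tests were checked on counts simulated from the libraries' own means and sizes with 200 genes changed, 100 by 2-fold and 100 by 4-fold. For the tumour CD71 comparison, run on 15742 genes, edgeR recovered 19 of the 2-fold and 57 of the 4-fold changes, with 6 false calls. For the culture CD71 comparison, run on 15511 genes, it recovered 27 and 67, with 9 false calls. For the difference, run on 15405 genes, it recovered 7 and 46, with 4 false calls. For tumour against culture it recovered 29 and 69 in the CD71− fraction (15570 genes, 6 false calls) and 34 and 86 in the CD71+ fraction (15315 genes, 11 false calls). A list planted as changed was recovered under both correlations, and no unchanged list was called. Genes were simulated independently of each other. The check could therefore not show false list calls that come from correlation between genes of a list. In this simulation most 2-fold changes were missed. With 200 genes changed, the small number of calls makes the adjusted threshold strict. Far more genes passed in each comparison below, so this recovery does not carry over to them. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.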

Results

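Gene expression was measured in 8 libraries of mouse neutrophils sorted by flow cytometry on CD71, the transferrin receptor that brings iron-loaded transferrin into cells. The cells came from brain tumours of the mouse glioma line SB28 or from cultures in which neutrophils were generated in vitro from naive bone marrow. Each origin gave 2 libraries labelled CD71− and 2 labelled CD71+. Total counts in the culture libraries were 13816733 and 9598959 for CD71− and 22615813 and 19385298 for CD71+. In the tumour libraries they were 11898224 and 11175405 for CD71− and 11713166 and 11147646 for CD71+. Principal components were computed on the most variable genes only. On the first, with 91.9% of the variance of these genes, tumour and culture libraries lay apart. On the second, with 5.31%, the sort fractions did. Mitochondrial transcripts took 7.09% and 12% of the counts in the culture CD71− libraries and 1.45% and 2.17% in the culture CD71+ libraries. In the tumour they took 0.413% and 0.202% in CD71− and 0.829% and 1.04% in CD71+. Adjusted p values below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for genes and from camera for gene lists.

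Tfrc, which encodes CD71 (ENSMUSG00000022797.16, chromosome 16, 32608920 to 32632794 on mm10), was examined in every library before any comparison. Its level was 131 and 94.3 CPM in the culture libraries labelled CD71− and 116 and 115 CPM in those labelled CD71+. In the tumour it was 187 and 145 CPM in the libraries labelled CD71− and 103 and 108 CPM in those labelled CD71+. The transcript thus did not follow the sort label, which reports surface protein. In culture its log2 fold change, CD71+ over CD71−, was 0.03 (SE 0.19, adjusted p = 0.93). In the tumour Tfrc fell by 0.65 with TMM (SE 0.19, adjusted p = 0.014), against the direction of the label, and without tumour CD71+ replicate 1 the adjusted p was 0.0765. With DESeq2 size factors the tumour fall of Tfrc still passed. Scaled by total counts, the tumour value was −0.08 (adjusted p = 0.765), and scaled on mature neutrophil genes it was 0.20 (adjusted p = 0.50), so the direction of the transcript is not settled. Fractions are therefore called by their labels throughout, and every direction drawn from the labels carries this limit.

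The study's question named 12 further genes, located here on mm10 with GENCODE M21. They are Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484), Vegfa (ENSMUSG00000023951.17, chromosome 17, 46016993 to 46032369), Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095) and Slc2a1 (ENSMUSG00000028645.11, chromosome 4, 119108711 to 119137983). With them stand Ldha (ENSMUSG00000063229.15, chromosome 7, 46841475 to 46855627), Hif1a (ENSMUSG00000021109.13, chromosome 12, 73901375 to 73947530), Ep300 (ENSMUSG00000055024.12, chromosome 15, 81585351 to 81652077) and Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139). The last are Cd14 (ENSMUSG00000051439.7, chromosome 18, 36725067 to 36726798), Olr1 (ENSMUSG00000030162.14, chromosome 6, 129485244 to 129507165), Tnfrsf10b (ENSMUSG00000022074.6, chromosome 14, 69767472 to 69784411) and Ly6g (ENSMUSG00000022582.4, chromosome 15, 75155240 to 75159126).

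**Figure D1:**
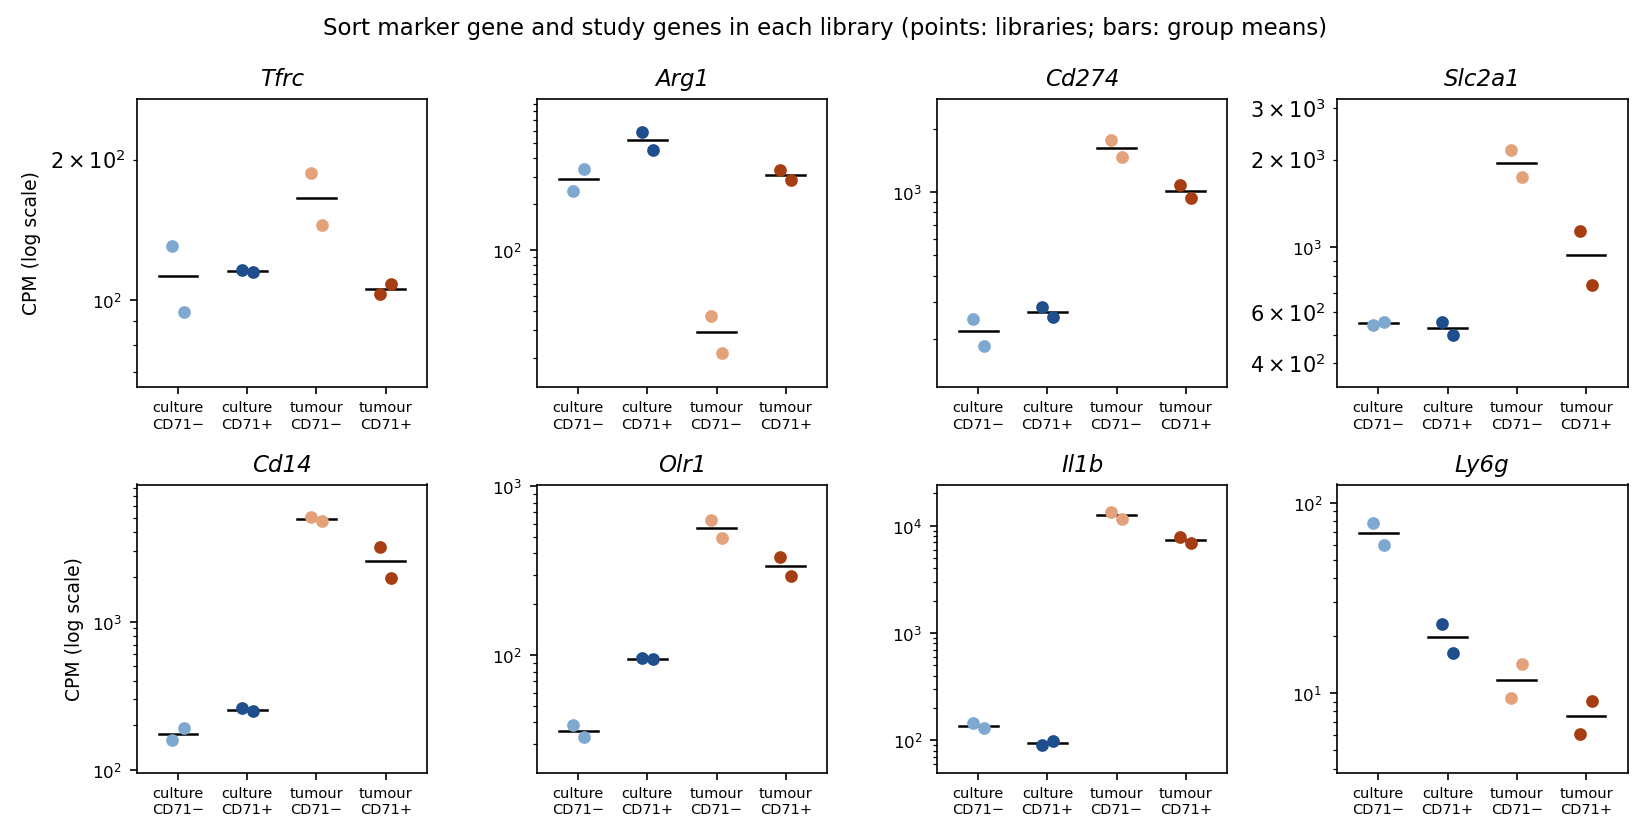
CPM (log scale) of Tfrc, Arg1, Cd274, Slc2a1, Cd14, Olr1, Il1b and Ly6g in the 8 libraries, grouped by origin and sort label; points are libraries and bars are means of 2 libraries. Arg1 lay at 29.3 CPM in the tumour libraries labelled CD71− and at 309.9 CPM in those labelled CD71+, while Tfrc did not follow the label.

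The tumour comparison asked how neutrophils with surface CD71 differ from those without it inside the tumour. Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from 29.3 ± 11.3 to 309.9 ± 32.5 CPM (SD, n = 2 per group), a log2 fold change of 3.40 (SE 0.27, adjusted p = 2.5e-06). Mrc1, the mannose receptor of macrophages, rose with it from 4.11 ± 0.514 to 78.4 ± 15.7 CPM. Csf3r, the receptor for the neutrophil growth factor G-CSF, fell from 5556 ± 316 to 2148 ± 214 CPM, by 1.37 on the log2 scale (SE 0.18, adjusted p = 9.2e-05). Of 15975 genes tested, 7037 passed, 4169 higher and 2868 lower in the libraries labelled CD71+. Mature neutrophil genes stood among those that fell, and markers of macrophages, microglia, dividing cells and neural cells among those that rose.

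Several genes tied to the suppressive function of tumour neutrophils fell in the tumour libraries labelled CD71+. Slc2a1, the glucose transporter GLUT1, fell by 1.05 (SE 0.20, adjusted p = 0.0012), and Cd14, the co-receptor for bacterial lipopolysaccharide, fell by 0.94 (SE 0.21, adjusted p = 0.0029). Il1b, which encodes the cytokine interleukin 1 beta, fell from 12480 ± 1390 to 7358 ± 582 CPM (adjusted p = 0.0031), and Cd274, which encodes the checkpoint ligand PD-L1, from 1617 ± 220 to 1009 ± 98.4 CPM (adjusted p = 0.0093). Olr1, the scavenger receptor LOX-1, fell by 0.74 (adjusted p = 0.0055), and Vegfa, the angiogenic factor, by 0.59 (adjusted p = 0.039). Ldha (lactate dehydrogenase A), Hif1a (the hypoxia-induced transcription factor subunit) and Ep300 (an acyltransferase of histones) had log2 fold changes of −0.45, −0.33 and −0.39 and did not pass (adjusted p = 0.067, 0.12 and 0.084). Nor did the death receptor gene Tnfrsf10b at −0.67 (adjusted p = 0.092) and the neutrophil surface marker gene Ly6g at −0.64 (adjusted p = 0.11). Exons of Cd274, Hif1a and Il1b overlap genes on the opposite strand, so their counts are uncertain. With DESeq2 size factors all 5 passed as lower, Ldha at −0.67 (adjusted p = 0.00994), Hif1a at −0.55 (0.0134), Ep300 at −0.62 (0.011), Tnfrsf10b at −0.88 (0.0281) and Ly6g at −0.86 (0.0364). Scaled on mature neutrophil genes, Hif1a (0.53, 0.0255) and Ep300 (0.47, 0.0489) passed as higher instead. With the 4 tumour libraries alone Ldha (0.0139) and Hif1a (0.0465) passed as lower. Scaled by total counts, Cd274 (−0.12, adjusted p = 0.643), Il1b (−0.20, 0.373), Cd14 (−0.39, 0.119), Olr1 (−0.18, 0.45) and Vegfa (−0.03, 0.925) no longer passed, nor did Slc2a1 (−0.20, 0.485) when scaled on mature neutrophil genes; with no filter Vegfa also missed (0.0548). Leaving out culture CD71+ replicate 1 or 2, tumour CD71− replicate 1 or tumour CD71+ replicate 2 also ended the call of Vegfa (adjusted p = 0.0582, 0.0578, 0.193 and 0.153). Ldha passed without culture CD71− replicate 1 or 2 (0.0308 and 0.0291), Ep300 without either of these or tumour CD71− replicate 1 (0.0411, 0.0393 and 0.0209), and Ly6g without tumour CD71− replicate 1 or tumour CD71+ replicate 2 (0.0383 and 0.0397).

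Among the largest rises in the tumour libraries labelled CD71+ were those of Mir99ahg, Eya4, Flrt3, Gpr34, Mrc1, Ms4a7 and Cenpf, with log2 fold changes from 4.19 to 4.69. Gpr34 is a receptor of microglia, Ms4a7 is expressed in macrophages, and Cenpf encodes a centromere protein of dividing cells. Cenpf stood at 0.697 ± 0.397 CPM in the CD71− libraries and at 12.8 ± 3.57 CPM in the CD71+ libraries. Among the largest falls, from −2.30 to −1.78, were those of Ovgp1, Pde6h, Carns1, Mir192, Sfn, Musk and Krt86. Scaled on mature neutrophil genes, Carns1 (−1.08, adjusted p = 0.138) and Krt86 (−0.92, 0.067) no longer passed. Pde6h, an inhibitory subunit of a cone photoreceptor phosphodiesterase, went from 22.3 to 4.81 CPM, but shares exons with Arhgdib on the opposite strand. Ovgp1 and Carns1 overlap other genes on the same strand, so their values are uncertain.

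Markers of other cells rose as groups in the tumour libraries labelled CD71+. Of 20 macrophage and monocyte genes, 16 rose and none fell, as many when adjusted over the list alone (median log2 fold change 3.05, adjusted p = 4.48e-25; adjusted p = 0.0918 with an estimated correlation). The tumour CD71− libraries already held 18 of these 20 genes at 5 CPM or more. Among 10 microglia genes 9 rose, also when adjusted over the list alone (median 3.33, adjusted p = 1.93e-15; adjusted p = 0.194 with an estimated correlation). Siglech, a lectin of microglia and plasmacytoid dendritic cells, rose from 3.61 ± 0.767 to 52.1 ± 17.2 CPM. Of 14 glioma and neural genes 10 rose (10 adjusted over the list alone; adjusted p = 0.00761; adjusted p = 0.525 with an estimated correlation), among them the astrocyte glutamate transporter gene Slc1a3, from 1.46 to 15.7 CPM. Of 10 dendritic cell genes 6 rose (6 adjusted over the list alone; adjusted p = 0.00984; adjusted p = 0.347 with an estimated correlation). Of 10 endothelial and stromal genes 6 rose and 1 fell (the same numbers adjusted over the list alone), and the list did not pass (adjusted p = 0.138) except without tumour CD71− replicate 1 or tumour CD71+ replicate 2 (0.0335 and 0.0198). Pdgfrb of pericytes rose from 2.16 to 11.4 CPM and Kdr of endothelium from 0.626 to 8.05 CPM.

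Of 25 mature neutrophil genes, 20 fell and none rose in the tumour libraries labelled CD71+, and 24 fell when adjusted over the list alone (median −0.92, adjusted p = 4.38e-09; adjusted p = 0.431 with an estimated correlation). With total counts 5 of the 25 fell (median −0.37). Besides Csf3r, Stfa2l1 fell by 1.16 (adjusted p = 0.0012; 0.0555 with total counts), but it belongs to a family of near-identical stefin genes. The fall of this list moved with the rise of 16 of 20 macrophage and 9 of 10 microglia genes. Of 20 NADPH oxidase and phagocytosis genes, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of −0.52 that became 0.04 when scaled by total counts, where 3 fell and 3 rose (adjusted p = 0.0155, and 0.229 with total counts; adjusted p = 0.525 with an estimated correlation). Fcgr1, a high-affinity immunoglobulin receptor also found on macrophages, rose by 3.01 within it. Of 24 suppressive neutrophil markers 13 fell and 3 rose, the same numbers adjusted over the list alone (adjusted p = 0.00761, and 0.0827 with total counts; adjusted p = 0.525 with an estimated correlation), with a median of −0.67 that became 0.19 when scaled on mature neutrophil genes; with total counts 4 fell and 5 rose. Arg2 and Jaml fell by 1.15 and 1.17, and Havcr2, which encodes the inhibitory receptor TIM-3, rose by 1.09 with Arg1. Scaled on mature neutrophil genes, Arg2 (−0.29, adjusted p = 0.238) and Jaml (−0.32, 0.216) no longer passed. Arg2 overlaps genes on the opposite strand. Of 20 immediate early and heat shock genes 10 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.00414; adjusted p = 0.528 with an estimated correlation), with a median of −0.57 that became 0.28 when scaled on mature neutrophil genes; with total counts 0 fell and 3 rose.

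The hypoxia response list fell in the tumour libraries labelled CD71+, with a median of −0.55 (mean −0.06, adjusted p = 0.012), but its median was 0.01 when scaled by total counts. With an estimated correlation the adjusted p = 0.628. Of its 35 tested genes, 19 fell and 4 rose (19 and 5 adjusted over the list alone), but with total counts 3 fell and 10 rose, and scaled on mature neutrophil genes 0 fell and 12 rose. Plaur, the urokinase receptor gene, fell by 1.13 and Pfkfb4, an enzyme that sets the level of a glycolysis activator, by 1.10. Selenbp1, a selenium-binding protein gene, rose by 3.02 (SE 0.58, adjusted p = 0.0014). Of 24 glycolysis and lactate genes 10 fell and 4 rose (12 and 4 adjusted over the list alone), and the list did not pass (median −0.41, mean 0.01, adjusted p = 0.0758; adjusted p = 0.725 with an estimated correlation); scaled by total counts the median was 0.14, with 3 genes lower and 7 higher, and scaled on mature neutrophil genes 1 was lower and 11 were higher. It passed without tumour CD71− replicate 2 (adjusted p = 0.0342) or tumour CD71+ replicate 1 (adjusted p = 0.027), with DESeq2 size factors (0.0454) and with no filter (0.0494). Slc2a3, the glucose transporter GLUT3, fell by 1.39 and Slc16a3, the lactate exporter MCT4, by 1.25, while Ldhb, the lactate dehydrogenase subunit B, rose from 3.41 to 25.2 CPM. Scaled on mature neutrophil genes, Plaur (−0.29, adjusted p = 0.362), Pfkfb4 (−0.25, 0.371) and Slc16a3 (−0.40, 0.248) no longer passed. Dilution cannot be read from these values alone, and the fall of the mature neutrophil list, with a median of −0.92, stood beside them.

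Growth genes rose in the tumour libraries labelled CD71+ under each of the scalings tried. Of 30 cell cycle genes 20 rose and none fell, 22 when adjusted over the list alone (median 1.56, adjusted p = 3.04e-05; adjusted p = 0.525 with an estimated correlation). Mcm3, a subunit of the replicative helicase, rose from 1.67 ± 0.796 to 15.1 ± 3.87 CPM. Of 28 Myc and ribosome biogenesis genes 19 rose, also when adjusted over the list alone (median 1.38, adjusted p = 3.51e-06; adjusted p = 0.525 with an estimated correlation), and Utp20 of the small ribosomal subunit processome rose by 2.66. Of 38 nuclear-encoded oxidative phosphorylation genes 21 rose, 24 when adjusted over the list alone (median 0.85, adjusted p = 0.00554; adjusted p = 0.646 with an estimated correlation). Of 19 antigen presentation genes 10 rose and 4 fell (10 and 5 adjusted over the list alone; median 0.66, adjusted p = 0.0351; adjusted p = 0.628 with an estimated correlation), with H2-DMb1, a chaperone of class II peptide loading, rising by 3.15. That list no longer passed without tumour CD71− replicate 2, tumour CD71+ replicate 1 or tumour CD71+ replicate 2 (adjusted p = 0.161, 0.199 and 0.0587), or with DESeq2 size factors (0.063), no filter (0.0544) or a stricter filter (0.0574). Macrophage markers, with a median of 3.05, moved with all 4 of these lists.

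The number of calls in the tumour comparison held within 1.5 times when each library was left out, except for 4488 without tumour CD71− replicate 2, and 4678 genes also changed at least 2-fold. The split depended on the scaling: 59.2% of calls were higher with TMM, 46.3% with DESeq2 size factors (3408 higher, 3955 lower) and 92.7% with total counts (6714 higher, 529 lower). The median of all genes shifted by −0.22 and 0.56 with DESeq2 size factors and total counts. Scaled by TMM, 13 of 27 lists passed.

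**Figure D2:**
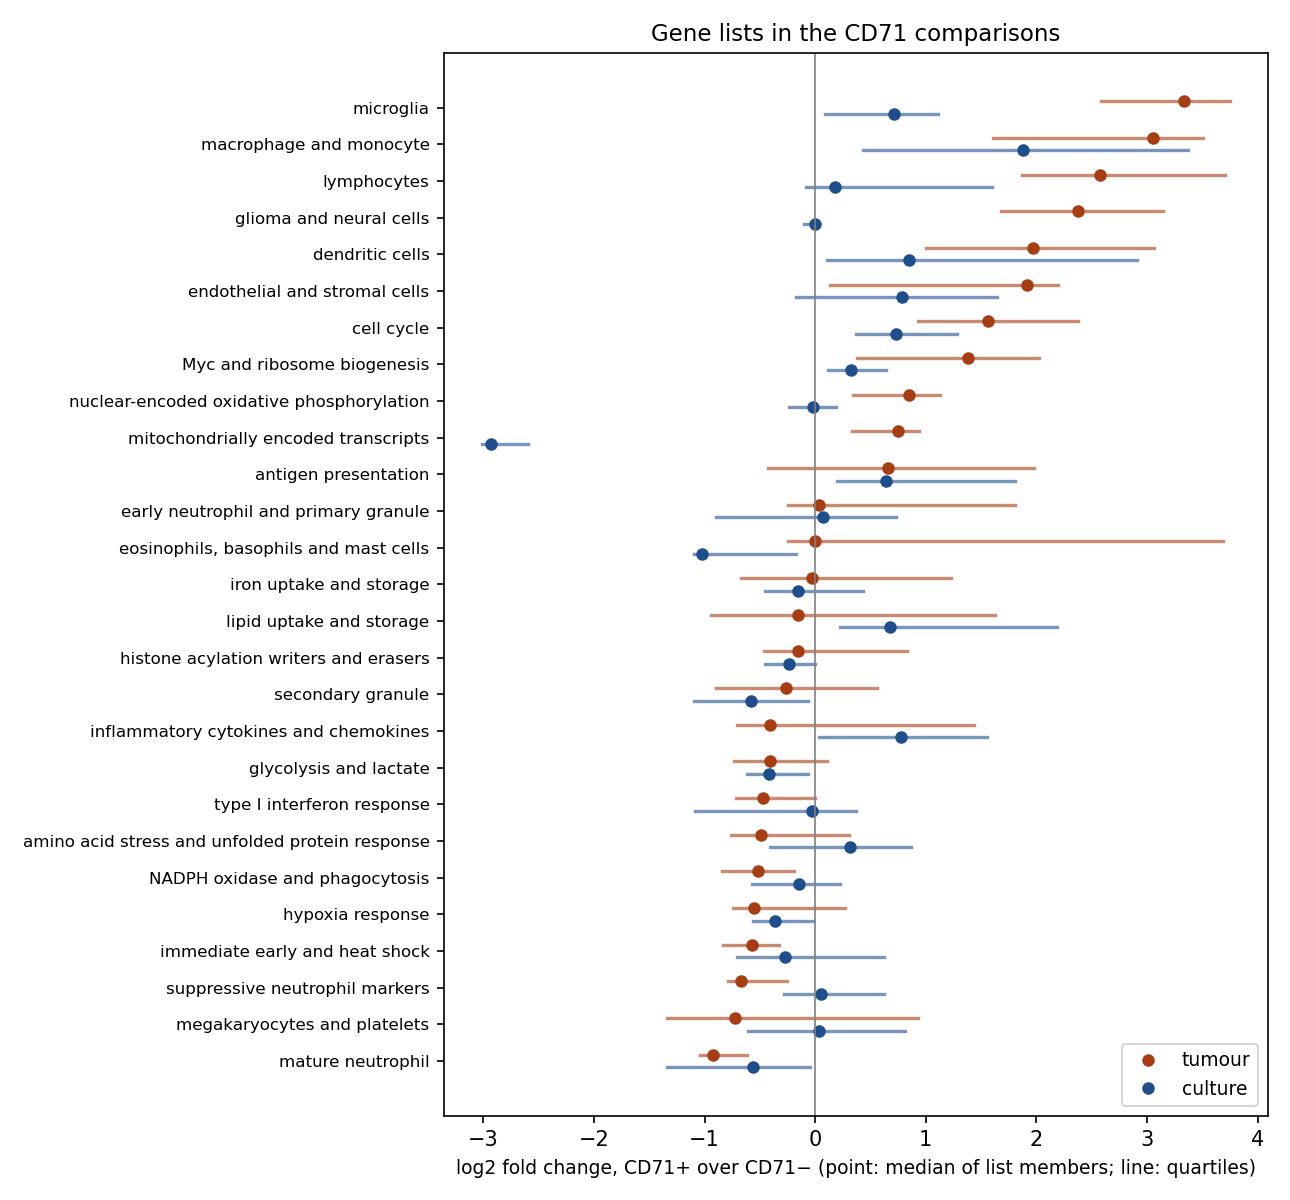
Log2 fold change of gene lists, CD71+ over CD71− libraries, in the tumour (red) and in culture (blue); points are medians over the tested genes of each list and lines run between the quartiles of its genes. Macrophage (median 3.05 in the tumour) and microglia genes lie highest and mature neutrophil genes (−0.92) lowest in the tumour, while the tumour medians of the hypoxia response, NADPH oxidase, glycolysis, interferon, unfolded protein response, cytokine, lipid, iron, histone and secondary granule lists lie below 0 here and above 0 when scaled by total counts.

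The culture comparison asked the same of neutrophils generated in vitro. Mgl2, a lectin of macrophages and dendritic cells, rose from 5.86 ± 2.35 to 105.9 ± 3.86 CPM in the libraries labelled CD71+ (SD, n = 2 per group), a log2 fold change of 4.21 (SE 0.28, adjusted p = 6.4e-07). Olr1 rose from 35.8 ± 4.33 to 95.2 ± 1.26 CPM, by 1.41 (SE 0.19, adjusted p = 0.00027). Csf3r fell by 2.33 (SE 0.19, adjusted p = 5.8e-06) and Ly6g by 1.81 (SE 0.25, adjusted p = 0.00029). Mitochondrially encoded transcripts fell, with mt-Rnr1, the small mitochondrial ribosomal RNA, going from 12050 ± 3640 to 667 ± 231 CPM. The library kit removes ribosomal RNA, so levels of mitochondrial ribosomal RNA may also reflect what that step left. Of 15975 genes tested, 3071 passed, 1559 higher and 1512 lower.

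Arg1 rose in culture from 289.5 ± 68.4 to 519 ± 97.0 CPM, by 0.84 on the log2 scale (SE 0.24, adjusted p = 0.027), but not without culture CD71− replicate 1 (adjusted p = 0.127), without culture CD71+ replicate 1 (0.226) or with the 4 culture libraries alone (0.0596). Vegfa fell by 0.68 (adjusted p = 0.041), with adjusted p = 0.153, 0.242 and 0.135 without culture CD71− replicate 2, culture CD71+ replicate 1 and culture CD71+ replicate 2. Il1b fell by 0.55 (adjusted p = 0.04), and this call ended without culture CD71− replicate 1, culture CD71+ replicate 1 or 2, tumour CD71− replicate 1 or 2, or tumour CD71+ replicate 1 (0.0706, 0.239, 0.13, 0.0525, 0.0547 and 0.0656). Scaled by total counts, Vegfa stood at −0.36 (adjusted p = 0.196) and Il1b at −0.24 (adjusted p = 0.334), and with the 4 culture libraries alone both missed (0.0643 and 0.051). Both also missed with no filter (0.0654 and 0.05), as did Vegfa with a stricter filter (0.0519) and Il1b with edgeR's legacy dispersions (0.0502). Cd14, at 0.54, did not pass (adjusted p = 0.085), but with total counts it did (0.86, adjusted p = 0.00539), as did Cd274, at 0.31 with TMM (adjusted p = 0.27) and 0.61 with total counts (0.0287). Slc2a1 (−0.06, adjusted p = 0.89), Ldha (−0.25, 0.38), Hif1a (0.08, 0.80), Tnfrsf10b (0.21, 0.66) and Ep300 (−0.52, 0.053) did not pass either, although Ep300 did without culture CD71− replicate 2 (0.0192), with DESeq2 size factors (0.0354), in DESeq2 (0.0213) and in limma-voom (0.0363).

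The largest rises in culture, with log2 fold changes from 3.63 to 4.69, were in Scd1, Il2ra, Mgl2, AI504432, Axl, Fcrls, Fads2 and Mmp12. Scd1 and Fads2 encode fatty acid desaturases, Axl is a receptor that binds apoptotic cells, and Mmp12 is the macrophage elastase, which went from 31.1 to 386 CPM. The largest falls, from −4.66 to −3.83, were in Snora57, mt-Rnr1, Snora23, Rn7s6, mt-Nd4l, Tchh, Calr4 and mt-Rnr2, most of them non-coding or mitochondrial. Rn7s6 lost its call without culture CD71+ replicate 1 or 2 (adjusted p = 0.0934 and 0.0617), and mt-Nd4l overlaps mt-Nd4.

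Macrophage and lipid genes rose together in the culture libraries labelled CD71+. Of 20 macrophage and monocyte genes 13 rose and none fell, 16 when adjusted over the list alone (median 1.88, or 1.36 with genes at 0 counts set to their bounds; adjusted p = 6.86e-17; adjusted p = 0.236 with an estimated correlation). C1qb of complement went from 1 count in the CD71− libraries to 92 counts in the CD71+ libraries. Of these 20 genes, the culture CD71− libraries held 11 at 5 CPM or more. Of 10 microglia genes 5 rose, also when adjusted over the list alone (median 0.71, adjusted p = 0.00113; adjusted p = 0.396 with an estimated correlation), among them Fcrls, and of 10 dendritic cell genes 4 rose, with Clec10a going from 1.87 to 16.6 CPM (4 adjusted over the list alone; adjusted p = 0.000864; adjusted p = 0.236 with an estimated correlation). Of 24 lipid uptake and storage genes 12 rose and 1 fell (13 and 3 adjusted over the list alone; median 0.67, adjusted p = 5.7e-08; adjusted p = 0.38 with an estimated correlation). Fabp4, a fatty acid carrier, went from 0.134 to 2.29 CPM. Of 23 cytokine and chemokine genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.77, adjusted p = 1.28e-05; adjusted p = 0.236 with an estimated correlation), with Cxcl16 rising from 0.657 to 6.62 CPM. Of 19 antigen presentation genes 9 rose and 1 fell, also when adjusted over the list alone (adjusted p = 4.53e-07; adjusted p = 0.38 with an estimated correlation), H2-Eb1 by 3.21. Of 30 cell cycle genes 12 rose (14 adjusted over the list alone; median 0.73, adjusted p = 6.74e-06; adjusted p = 0.396 with an estimated correlation), Cenpf by 3.54 and the mitotic kinase gene Aurkb by 2.22.

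Of 25 mature neutrophil genes 12 fell and 1 rose in the culture libraries labelled CD71+ (15 and 1 adjusted over the list alone; median −0.57, adjusted p = 1.68e-09; adjusted p = 0.284 with an estimated correlation), with Retnlg falling from 157 ± 48.2 to 18.7 ± 5.32 CPM. Of 18 secondary granule genes 6 fell and 2 rose (8 and 3 adjusted over the list alone; median −0.58, adjusted p = 0.0111; adjusted p = 0.66 with an estimated correlation), and this list no longer passed without culture CD71+ replicate 2 (adjusted p = 0.0776). The hypoxia response list fell, with a median of −0.36 that was −0.06 when scaled by total counts, where it no longer passed (adjusted p = 0.00678 and 0.0655; adjusted p = 0.672 with an estimated correlation). Of its 35 genes 11 fell and 3 rose, the same numbers adjusted over the list alone, with Pfkfb3, an activator of glycolysis, falling by 1.10. With total counts 3 of these genes fell and 4 rose. Without culture CD71+ replicate 2 the list's median was −0.25 (adjusted p = 0.0922). The glycolysis and lactate list fell too, with 6 genes lower and 2 higher of 24 (7 and 2 adjusted over the list alone; median −0.42, adjusted p = 0.0138; adjusted p = 0.697 with an estimated correlation). Scaled by total counts its median was −0.10, with 2 genes lower and 2 higher (camera adjusted p = 0.0474). Slc2a3 fell by 1.39 and the hexokinase gene Hk3 by 1.33. It did not pass without culture CD71− replicate 2 (median −0.18, adjusted p = 0.182) or culture CD71+ replicate 2 (−0.22, 0.188). Of 13 mitochondrially encoded transcripts 12 fell, 13 when adjusted over the list alone (median −2.93, adjusted p = 7.28e-21; adjusted p = 0.236 with an estimated correlation). Ribosomal RNA genes took 0.211% and 2.84% of counts in the culture CD71− libraries and 0.373% and 0.923% in the CD71+ libraries.

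Calls in the culture comparison fell to 1000 and 1230 without culture CD71+ replicate 1 and 2, and 1796 of the genes changed at least 2-fold. With total counts 81.9% of calls were higher (3265 higher, 721 lower) against 50.8% with TMM, and the median of all genes shifted by 0.31. With TMM 12 of 27 lists passed.

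To ask whether CD71 marks the same genes in both settings, the 2 comparisons, which share no library, were overlapped. In the same direction, 1674 genes passed in both, 919 higher and 755 lower, where independent lists of these sizes would share 406.9 and 271.5. In opposite directions, 98 rose in the tumour and fell in culture and 99 the reverse, where independent lists would share 394.6 and 279.9. The number in opposite directions was larger without culture CD71− replicate 1 and smaller without either culture CD71+ replicate. Csf3r, Cenpf, Jaml and Slc40a1, the iron exporter ferroportin, were among genes that passed in the same direction in both. Across genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.357 and Spearman's 0.391. Without culture CD71+ replicate 1 or 2 the shared count was 606 or 723.

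The difference between the CD71 effects was then tested itself. Arg1 rose more in the tumour than in culture, by a log2 difference of 2.56 (SE 0.35, adjusted p = 0.00094), from tumour and culture effects of 3.40 and 0.84. Olr1 differed by −2.15 (SE 0.27, adjusted p = 0.00043) and Cd14 by −1.48 (SE 0.30, adjusted p = 0.0056). Of 15975 genes tested, 2444 passed, 1685 with a higher and 759 with a lower effect in the tumour. Cd274 (−0.99, adjusted p = 0.023) and Slc2a1 (−0.99, adjusted p = 0.033) also passed. Cd274 did not pass without culture CD71+ replicate 1 or 2, tumour CD71− replicate 1 or tumour CD71+ replicate 2 (0.103, 0.0601, 0.0563 and 0.0538). Slc2a1 did not pass without these (0.123, 0.0801, 0.0885 and 0.0708) or without tumour CD71− replicate 2 (0.0516), and neither passed when scaled by total counts (0.0689 and 0.0637). Tfrc (−0.68, adjusted p = 0.098), Ly6g (1.18, 0.058), Hif1a (−0.41, 0.27), Tnfrsf10b (−0.88, 0.18), Vegfa (0.09, 0.89), Ldha (−0.20, 0.66), Ep300 (0.12, 0.79) and Il1b (−0.21, 0.61) did not. Tfrc passed without culture CD71− replicate 1 (0.0152), with DESeq2 size factors (−0.86, 0.0401) and in DESeq2 (0.0243), so the call of the sort marker's own difference depends on scaling. Ly6g passed without culture CD71− replicate 2 (0.0402) or tumour CD71+ replicate 1 (0.0457) and with total counts (0.0236).

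The most positive differences were in AU022793, C4b, Ifi205, Fbn1 and Lrrc3, and the most negative in Cxcl1, Mamstr, Pla1a, Scd1 and Mir155hg. Pla1a, a phospholipase, had a difference of −3.55 (SE 0.54, adjusted p = 0.0011). C4b of complement went from 14.6 ± 0.865 to 198 ± 49.3 CPM in the tumour and from 4 to 1 counts in culture. Most of the others rest on very low counts in a group, and their calls depended on single libraries. Without culture CD71− replicate 1 the adjusted p was 0.167 for C4b, 0.182 for Lrrc3, 0.0524 for Cxcl1, 0.09 for Mamstr and 0.0775 for Scd1. Without culture CD71− replicate 2 it was 0.0635 for AU022793, 0.134 for Ifi205, 0.0749 for Fbn1, 0.0712 for Mamstr and 0.0808 for Scd1. Without culture CD71+ replicate 1 it was 0.0963 for AU022793, 0.0762 for Ifi205, 0.0554 for Fbn1, 0.0748 for Mamstr and 0.0506 for Scd1. Without culture CD71+ replicate 2 it was 0.0797 for AU022793, 0.14 for Mamstr and 0.058 for Mir155hg. Without tumour CD71− replicate 1 it was 0.147 for AU022793, 0.0623 for Mamstr and 0.0675 for Scd1, without tumour CD71− replicate 2 it was 0.161 for AU022793 and 0.075 for Mamstr, and without tumour CD71+ replicate 2 it was 0.0842 for AU022793. With no filter it was 0.0637 for AU022793 and 0.0519 for Mamstr.

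Lists whose CD71 effect was higher in the tumour were microglia (median difference 2.44, adjusted p = 0.0104), Myc and ribosome biogenesis (1.25, 4.56e-05), nuclear-encoded oxidative phosphorylation (0.78, 0.000446), mitochondrially encoded transcripts (3.32, 1.22e-12) and macrophage and monocyte genes (0.23, 0.0483). In these lists 4 of 10, 10 of 28, 8 of 38, 9 of 13 and 6 of 20 genes passed as higher. Adjusted over the list alone 4, 16, 14, 11 and 6 did. Only the macrophage list held genes that passed as lower, 2 in either count. The mitochondrially encoded list was written as a check of sample quality. Its CD71 effect had a median of −2.93 in culture and 0.75 in the tumour, where it did not pass (camera adjusted p = 0.52). Lists with a lower effect were cytokines and chemokines (−0.98, 2.8e-05), lipid uptake and storage (−0.92, 4.56e-05), suppressive neutrophil markers (−0.70, 0.000386), amino acid stress and unfolded protein response (−0.51, 0.00288) and immediate early and heat shock genes (−0.32, 0.000988). In these 11 of 23, 8 of 24, 8 of 24, 5 of 23 and 4 of 20 genes passed as lower and 1, 2, 2, 1 and 0 as higher; adjusted over the list alone 13, 13, 9, 5 and 6 were lower and 2, 2, 3, 2 and 0 higher. Over these 10 lists the lowest adjusted p = 0.651 with an estimated correlation, and fry called 0 of the 27 lists for the difference. The hypoxia and glycolysis lists did not pass (medians 0.03 and 0.15, both with a test direction of down; adjusted p = 0.635 and 0.931), and both medians fell below 0 with DESeq2 size factors. The macrophage list lost its call without culture CD71− replicate 2, culture CD71+ replicate 2, tumour CD71− replicate 1, or tumour CD71+ replicate 1 or 2 (0.062, 0.207, 0.107, 0.178 and 0.264), with DESeq2 size factors (median 0.05, 0.0651), with no filter (0.0994) and with a stricter filter (0.134), and its median ran from −0.03 to 0.53 when libraries were left out. The microglia list lost its call without tumour CD71− replicate 1 or tumour CD71+ replicate 2 (0.0514 and 0.0786). The count of 2444 genes was 919 and 910 without culture CD71+ replicate 1 and 2, 1127 and 857 without tumour CD71− replicate 1 and 2, and 1394 without tumour CD71+ replicate 2. With DESeq2 size factors 50.3% of calls were higher (1257 and 1241) and with total counts 87.0% (2643 and 396), against 68.9% with TMM, and the median of all genes shifted by −0.17 and 0.25.

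Tumour and culture libraries were compared within each fraction. Origin is bound to cell source and preparation in this design, so these differences belong to the whole of it. In the CD71− fraction Il1b rose from 138 ± 9.95 CPM in culture to 12480 ± 1390 CPM in the tumour (SD, n = 2 per group), by 6.50 (SE 0.22, adjusted p = 4.9e-11). Cd14 rose by 4.82 (SE 0.25, adjusted p = 1.0e-09), Olr1 by 3.97 (SE 0.21, adjusted p = 1.4e-09), Cd274 by 2.89 (SE 0.20, adjusted p = 2.0e-08) and Hif1a by 2.81 (SE 0.18, adjusted p = 8.9e-09). Arg1 fell by 3.30 (SE 0.27, adjusted p = 2.5e-07) and Ly6g by 2.56 (SE 0.28, adjusted p = 2.1e-06). Of 15975 genes tested, 10655 passed, 4825 higher and 5830 lower in the tumour.

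Slc2a1 rose by 1.82 (adjusted p = 3.4e-06) and Tnfrsf10b by 1.38 (adjusted p = 0.0015; 0.231 with total counts) in the CD71− fraction, whereas Vegfa (0.16, adjusted p = 0.53), Ldha (0.09, 0.69) and Ep300 (−0.37, 0.079) did not pass; scaled by total counts Vegfa, Ldha and Ep300 were lower in the tumour (−0.77, −0.83 and −1.29). Tfrc was higher by 0.56 (adjusted p = 0.018) but stood at −0.38 with total counts, and its adjusted p was 0.116 without culture CD71− replicate 2 and 0.0768 with no filter. Ep300 passed without that library (0.0233) and with no filter (0.0442). Several genes had counts in the tumour and none in the culture CD71− libraries. Efr3b was at least 771-fold higher, Cxcl1, a chemokine that draws neutrophils, at least 414-fold, Astl at least 291-fold, C1qa at least 179-fold, Csf3, the gene of G-CSF itself, at least 176-fold, Muc3 at least 168-fold, Mamstr at least 152-fold and Bgn at least 97.2-fold. The reverse held for Klk1b11, at least 130-fold lower, Prg2 and Epx, granule genes of eosinophils, at least 119-fold and 31.3-fold lower, AU022793 (106-fold), Scd4 (49-fold), Fgf23 (42.4-fold) and Cyp11a1 (25.5-fold), each as a lower bound. Klk1b11 and Scd4 have near-identical relatives and are uncertain. Pde1c went from 63.9 CPM to 1 count.

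Inflammatory, stress and mature neutrophil lists were higher in the tumour CD71− fraction under each scaling tried. Other maturation lists were not, with TMM medians of −0.75 for secondary granule genes and −0.12 for early neutrophil and primary granule genes. The immediate early and heat shock list was written as a check of sample quality. Its rise cannot be told apart from preparation, which is bound to origin here. Of 24 type I interferon genes 23 rose, also when adjusted over the list alone (median 4.26, adjusted p = 6.62e-25; adjusted p = 0.0236 with an estimated correlation), with the antiviral gene Rsad2 going from 1.84 to 1564 CPM. Of 23 cytokine and chemokine genes 20 rose and none fell, also when adjusted over the list alone (median 5.19, or 4.77 at bounds, adjusted p = 4.31e-21; adjusted p = 0.0232 with an estimated correlation), with the interleukin 23 subunit gene Il23a going from 5 counts to 162 CPM. Of 20 immediate early and heat shock genes 19 rose, also when adjusted over the list alone (median 4.28, or 3.79 at bounds, adjusted p = 7.28e-22; adjusted p = 0.185 with an estimated correlation), with Fosb, a subunit of AP-1, going from 0.659 to 649 CPM. Of 24 suppressive neutrophil markers 20 rose and 1 fell (20 and 2 adjusted over the list alone; median 2.49, adjusted p = 1.49e-10; adjusted p = 0.212 with an estimated correlation). Ptgs2, the cyclooxygenase of prostaglandin E2 synthesis, went from 16.0 to 7644 CPM, while Arg1 fell. Of 25 mature neutrophil genes 21 rose and 1 fell (22 and 1 adjusted over the list alone; median 1.72, adjusted p = 1.08e-08; adjusted p = 0.294 with an estimated correlation), G0s2 by 8.06 and Trem1 by 5.03. Of 23 amino acid stress and unfolded protein genes 17 rose and 2 fell, also when adjusted over the list alone (adjusted p = 5.66e-10; adjusted p = 0.212 with an estimated correlation), with the cystine transporter gene Slc7a11 rising by 6.28, and of 20 NADPH oxidase and phagocytosis genes 16 rose and 2 fell, also when adjusted over the list alone (adjusted p = 7.1e-05; adjusted p = 0.294 with an estimated correlation).

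Other-cell markers also differed by origin in the CD71− fraction. Of 20 macrophage and monocyte genes 13 were higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.00141; adjusted p = 0.345 with an estimated correlation), and of 10 microglia genes 7 were higher and 1 lower, likewise adjusted over the list alone (median 3.55, or 3.41 at bounds; adjusted p = 0.00119; adjusted p = 0.345 with an estimated correlation). Of 14 glioma and neural genes 7 were higher, 6 adjusted over the list alone (median 5.08, or 2.55 at bounds; adjusted p = 0.0312; adjusted p = 0.574 with an estimated correlation), with the astrocyte gene Gfap at least 27.6-fold higher. This list lost its call without culture CD71− replicate 1 or tumour CD71− replicate 1 (0.0782 and 0.0993), with DESeq2 size factors (0.0526) and with a stricter filter (0.0669). Of 13 mitochondrially encoded transcripts all 13 fell, also when adjusted over the list alone (median −4.47, or −4.46 at bounds; adjusted p = 2.13e-06; adjusted p = 0.455 with an estimated correlation), and of 38 nuclear-encoded oxidative phosphorylation genes 28 fell and 1 rose, 30 and 1 adjusted over the list alone (median −1.15, adjusted p = 0.00487; adjusted p = 0.698 with an estimated correlation). The hypoxia list did not pass (median −0.69, adjusted p = 0.0805; adjusted p = 0.776 with an estimated correlation): 19 of 35 genes fell and 10 rose (19 and 12 adjusted over the list alone), Plaur and Hilpda of lipid droplets rising by 4.95 and 3.75, Stc2 going from 41.6 CPM to 1 count and Selenbp1 falling by 8.47. It passed without culture CD71− replicate 2 (0.0348) and with total counts (0.0126). The glycolysis list did not pass (median −0.05, or 0.20 with DESeq2 size factors; adjusted p = 0.252), with 8 genes higher and 10 lower of 24, also when adjusted over the list alone, and Aldoc falling by 6.07. With DESeq2 size factors the median of all genes shifted by 0.25, and with total counts by −0.93, where 25.1% of calls were higher (2973 and 8862) against 45.3% with TMM. Scaled by TMM, 16 of 27 lists passed.

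In the CD71+ fraction Il1b rose from 93.9 ± 5.64 CPM in culture to 7358 ± 582 CPM in the tumour (SD, n = 2 per group), by 6.29 (SE 0.22, adjusted p = 5.7e-11). Cd14 rose by 3.34 (SE 0.23, adjusted p = 2.2e-08), Hif1a by 2.40 (SE 0.18, adjusted p = 4.2e-08), Cd274 by 1.90 (SE 0.19, adjusted p = 1.2e-06) and Olr1 by 1.82 (SE 0.19, adjusted p = 1.6e-06). Ly6g fell by 1.38 (SE 0.28, adjusted p = 0.00067). Arg1 fell by 0.74 (SE 0.24, adjusted p = 0.017), but not without culture CD71+ replicate 1 or tumour CD71+ replicate 2 (0.145 and 0.139), and Slc2a1 rose by 0.83 (SE 0.20, adjusted p = 0.0028), but not without tumour CD71+ replicate 1 (0.0788) or with total counts (0.15, 0.494). Tfrc (−0.13, adjusted p = 0.58), Vegfa (0.25, 0.34), Ldha (−0.11, 0.63), Ep300 (−0.24, 0.24) and Tnfrsf10b (0.50, 0.14) did not pass, though Tfrc, Ldha and Ep300 did with total counts (−0.80, −0.79 and −0.92). Of 15975 genes tested, 9695 passed, 5017 higher and 4678 lower in the tumour.

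Among the largest rises in the CD71+ fraction, Nav3 was at least 1390-fold higher, Sall1, a transcription factor of microglia, at least 795-fold, Siglech at least 534-fold and Apod, an apolipoprotein of glia, at least 387-fold. Sparc stood at 288 ± 36.4 CPM and C4b at 198 ± 49.3 CPM against 1 count each in culture, Steap4, a metalloreductase, at 102 ± 18.1 CPM against 1 count, and Ifit3b at least 457-fold higher, although it has near-identical relatives. Klk1b11, Klk1b1, Fgf23, Gp6 of platelets and Pgr were at least 455-fold, 96.2-fold, 104-fold, 46.4-fold and 41.7-fold lower, with the Klk1b genes uncertain as close relatives. Pde1c, Ccn3 and Bpifc stood at 64.7, 210.4 and 13.6 CPM in culture and at 1, 4 and 1 counts in the tumour.

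All 10 microglia genes rose in the CD71+ fraction, also when adjusted over the list alone (median 3.45, adjusted p = 3.4e-12; adjusted p = 0.10 with an estimated correlation). Of 20 macrophage and monocyte genes 13 rose and 3 fell, also when adjusted over the list alone (median 2.13, adjusted p = 1.62e-09; adjusted p = 0.10 with an estimated correlation); C1qa went from 0.556 to 445 CPM, and Gpnmb fell by 2.12. Of 14 glioma and neural genes 13 rose, also when adjusted over the list alone (median 7.16, or 5.45 at bounds; adjusted p = 2.58e-05; adjusted p = 0.197 with an estimated correlation), with Slc1a3 at least 161-fold higher. Of 9 lymphocyte genes 8 rose, 9 adjusted over the list alone (median 3.62, adjusted p = 0.0482; adjusted p = 0.197 with an estimated correlation), but the list lost its call without culture CD71− replicate 1 or 2, culture CD71+ replicate 1, or tumour CD71− replicate 1 or 2 (0.0759, 0.0824, 0.0598, 0.0599 and 0.0593), and with DESeq2 size factors (0.0621). All 24 type I interferon genes rose, also when adjusted over the list alone (median 4.01, adjusted p = 8.27e-33; adjusted p = 0.0156 with an estimated correlation), with Rsad2 going from 1.47 to 936 CPM. Of 23 cytokine and chemokine genes 21 rose and 1 fell, also when adjusted over the list alone (median 4.46, adjusted p = 5.7e-22; adjusted p = 0.0548 with an estimated correlation). Of 25 mature neutrophil genes 20 rose and 1 fell (21 and 1 adjusted over the list alone; median 1.69, adjusted p = 1.95e-08; adjusted p = 0.187 with an estimated correlation), G0s2 by 7.66 and Retnlg by 4.09. Of 24 suppressive neutrophil markers 16 rose and 2 fell (16 and 3 adjusted over the list alone; median 1.86, adjusted p = 2.08e-08; adjusted p = 0.126 with an estimated correlation), Ptgs2 by 8.10.

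The hypoxia list was lower in the tumour CD71+ fraction, with a median of −0.66 (adjusted p = 0.00739; adjusted p = 0.578 with an estimated correlation). Of its 35 genes 19 fell and 11 rose, the same numbers adjusted over the list alone, with Plaur and Pfkfb3 rising by 2.88 and 2.86 and Stc2, a secreted glycoprotein, falling by 6.49. It did not pass without tumour CD71+ replicate 2 (median −0.61, adjusted p = 0.0688). The glycolysis list did not pass (median −0.28, adjusted p = 0.157), except without culture CD71+ replicate 2 (0.022), with Ldhb rising by 3.92 and Aldoc falling by 5.09 among 8 higher and 11 lower genes of 24 (8 and 12 adjusted over the list alone). Lpl, the lipoprotein lipase gene, fell by 4.50. With total counts the median of all genes shifted by −0.67 and 29.2% of calls were higher (3428 and 8298) against 51.8% with TMM. Scaled by TMM, 15 of 27 lists passed.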

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

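All tests of technical explanations in this part were chosen after the results were seen; the test of the difference between the CD71 effects was planned.

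The results below drew attention because the CD71 effect differed between tumour and culture by a test of that difference, edgeR's quasi-likelihood test for genes and camera for lists. In all, 2444 genes differed. Arg1 differed by 2.56, Cd274 by −0.99 (adjusted p = 0.023), Slc2a1 by −0.99 (adjusted p = 0.033), Cd14 by −1.48 and Olr1 by −2.15 on the log2 scale. The adjusted p was 0.036 for AU022793, 0.0089 for C4b, 0.015 for Ifi205, 0.011 for Fbn1, 0.007 for Lrrc3, 0.0093 for Cxcl1, 0.031 for Mamstr, 0.0011 for Pla1a, 0.018 for Scd1 and 0.013 for Mir155hg. Median differences of the lists were 0.23 for macrophage and monocyte, 2.44 for microglia, 1.25 for Myc and ribosome biogenesis, 0.78 for nuclear-encoded oxidative phosphorylation and 3.32 for mitochondrially encoded transcripts. They were −0.51 for amino acid stress and unfolded protein response, −0.98 for cytokines and chemokines, −0.92 for lipid uptake and storage, −0.70 for suppressive neutrophil markers and −0.32 for immediate early and heat shock genes. The mitochondrially encoded list, a check of sample quality, had median CD71 effects of −2.93 in culture and 0.75 in the tumour. With an estimated correlation none of these lists passed (lowest adjusted p = 0.651), and fry called 0 of 27 lists.

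In the tumour libraries labelled CD71+, markers of other cells rose while mature neutrophil genes fell. The tables argue against scaling as the cause of the rise. Over 3 scalings the macrophage median nearest to 0 was 2.83 (95% bootstrap interval over genes 2.03 to 3.25). For the fall, the neutrophil median nearest to 0 was −0.37 (−0.47 to −0.08), with total counts. An interval over genes does not cover error in the scaling, and another scaling could bring that median to 0. The neutrophil list still stood below the median of all genes, which was 0.69 with total counts. RNA from macrophages and other tumour cells that passed the sort stays open and was not decided: that 53 of 73 markers of 6 cell types rose, 72.6% against 26.1% of all genes tested, restates the pattern and could not tell its source. Of the 10 most abundant macrophage and microglia markers 9 rose, among them Fn1 from 217 to 1765, Apoe from 73.6 to 732 and C1qa from 40.3 to 445 CPM, while Cd68 went from 259 to 201 CPM; Fn1, Apoe, C1qa and Cd68 were picked after their values were seen. A neutrophil state tied to CD71 stays open as well and was not tested, and the sort gates were not given beyond the labels.

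The rise of Arg1 in these libraries was not a matter of scaling, since its lowest log2 fold change over 3 scalings was 3.19 (SE 0.27). RNA of macrophages and microglia could bring Arg1 along: 13 of their 30 markers had a larger fold change, and its value of 3.40 lay within the quartiles of their values, 2.35 to 3.64. Expression of Arg1 by CD71+ neutrophils themselves is equally open and was not tested.

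The hypoxia response list had a lower median in the tumour libraries labelled CD71+. Scaling sets whether that median lies under 0. From TMM to total counts it went from −0.55 (bootstrap interval −0.68 to −0.13) to 0.005 (−0.12 to 0.43), while the median of all genes went from 0.13 to 0.69. The list thus stayed below the median of all genes by a like amount, and the sign decides nothing. Why its camera call ended with total counts was not tested. Dilution of neutrophil RNA by other RNA stays open. The hypoxia list fell less than the mature neutrophil list, by a difference of medians of 0.37 (0.10 to 0.75). The mature neutrophil list had the lowest median of all lists in the tumour comparison, so this result could hardly fail and decides nothing. Scaled on mature neutrophil genes, the median of the hypoxia list was 0.32. A weaker or a stronger hypoxia response in cells with surface CD71 stays open, and neither was tested.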

How the results depend on the processing

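Scaling on the mature neutrophil list was chosen after the data were seen; the other alternatives were planned. Depth and 2 libraries per group limit what can be called, and leaving out a library left a group with 1, which is then assumed to vary like the others. Of the values recomputed for named genes, 4129 kept their sign and stayed on the same side of the threshold, passed or not. A further 117 lost and 40 gained a call, 10 with a call changed sign and 34 without a call did. For lists, judged by camera's direction and not by the sign of the median, these were 1731, 51, 52, 0 and 72. Medians of lists that passed did change sign. Hypoxia in the tumour, for example, stood at −0.55 with TMM and 0.32 when scaled on mature neutrophil genes. The cause of each change was not tested, except that leaving out samples removes information.

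A 2-fold minimum gave 4678 genes in the tumour and 1796 in culture, as fewer genes can pass. Leaving out each library gave 4488 to 7744 (tumour), 1000 to 3080 (culture), 857 to 3541 (difference), and 606 to 1852 shared genes. List medians then ran from −0.43 to −0.25 (hypoxia, culture), −0.57 to −0.18 (glycolysis, culture) and −0.52 to −0.38 (glycolysis, tumour). Glycolysis in the tumour passed at −0.63 with DESeq2 size factors (adjusted p = 0.0454) and −0.38 with no filter (0.0494). With total counts hypoxia no longer passed, at 0.00532 in the tumour and −0.0583 in culture. With an estimated correlation hypoxia, at −0.55 (tumour) and −0.36 (culture), and glycolysis, at −0.42 (culture), did not pass, and 0, 0, 0, 2 and 1 lists passed over the 5 comparisons. With scaling on the mature neutrophil list 8190 genes (8124 higher, 66 lower; median of all genes shifted by 0.85) and 7 lists passed in the tumour, where hypoxia stood at 0.32 and the dendritic, glioma, NADPH oxidase, suppressive and immediate early lists no longer passed (0.0734, 0.112, 0.57, 0.24 and 0.0562).

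Signs changed in tumour CD71 with that scaling for Tfrc (0.20), Vegfa (0.25), Cd274 (0.17), Hif1a (0.53, passing at 0.0255), Ep300 (0.47, passing at 0.0489), Il1b (0.0881) and Olr1 (0.10), and between tumour and culture in CD71− with total counts for Tfrc (−0.38), Vegfa (−0.77) and Ldha (−0.83).

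The labels do not say whether replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.0716 in the tumour and 0.0120 in culture. With 2 libraries per group these values cannot exclude shared animals, cultures or sort days. With a replicate block the calls were 7079 (tumour), 3368 (culture), 2641 (difference), 10656 and 9918, 1836 genes were shared, and glycolysis in the tumour passed at −0.43 (adjusted p = 0.0275). So did the interferon (0.0275) and lymphocyte (0.0174) lists there, while antigen presentation in the tumour (0.126), the macrophage list in the difference (0.216) and Mamstr (0.0566) no longer passed. Ly6g passed in the tumour (0.0478) and in the difference (0.0195), and Ep300 (0.0399) and Cd14 (0.0359) in culture.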

Other observations

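Scaling on mature neutrophil genes was chosen after the results were seen; the other tests here, the lists and the named-gene rule were planned.

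Iron and lipid genes moved both ways in the tumour libraries labelled CD71+. Of 19 iron uptake and storage genes 6 rose and 6 fell (8 and 8 adjusted over the list alone), and the list did not pass, with a median of −0.03, a mean of 0.35 and a test direction of up (adjusted p = 0.809). Slc11a2, the iron importer DMT1, rose by 2.72 (SE 0.25) and Slc40a1, the iron exporter ferroportin, fell by 1.13 (SE 0.18); in culture they moved by 1.32 and −1.28, and both passed. Scaled on mature neutrophil genes, Slc40a1 in the tumour was −0.28 (adjusted p = 0.288). With total counts the median of the iron list was 0.53 in the tumour. Of 24 lipid genes 10 rose and 11 fell in the tumour (11 and 12 adjusted over the list alone; median −0.16, mean 0.36, adjusted p = 0.81), with Lpl, the lipoprotein lipase, rising by 3.43 and Dgat1 of triglyceride synthesis falling by 1.49; the median was 0.40 with total counts. Of 23 cytokine and chemokine genes 7 rose and 9 fell in the tumour (7 and 11 adjusted over the list alone), and the list did not pass (median −0.41, or 0.15 with total counts; mean 0.71; adjusted p = 0.809). Of 24 type I interferon genes 4 rose and 11 fell there, also when adjusted over the list alone, and the list did not pass (median −0.47, or 0.09 with total counts; mean 0.12; adjusted p = 0.0892), but did without tumour CD71− replicate 1 or tumour CD71+ replicate 2 (0.0185 and 0.0349), with DESeq2 size factors (0.0478) and with no filter (0.0241). Within it Mx1 rose by 3.72 and Oas3 fell by 1.11, but stood at −0.25 (adjusted p = 0.37) when scaled on mature neutrophil genes.

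For genes that write or erase histone acylation the result depended on the test: fry called the list lower in culture (adjusted p = 0.0048) and higher in the tumour within the CD71+ fraction (0.0043, with a median of −0.12), and camera called it in no comparison. Of 22 such genes 5 rose and 5 fell in the tumour libraries labelled CD71+, also when adjusted over the list alone (median −0.16, or 0.40 with total counts; mean 0.19; adjusted p = 0.485), and 2 fell in culture, also when adjusted over the list alone (median −0.24, or 0.07 with total counts; adjusted p = 0.158). Kat6a, a lysine acetyltransferase, fell in culture by 0.79 (SE 0.16, adjusted p = 0.0031; 0.0524 with total counts). Between tumour and culture in the CD71− fraction 7 rose and 9 fell, also when adjusted over the list alone (median −0.33, adjusted p = 0.879), with Sirt1, a deacylase, rising by 2.51 and Hdac8 falling by 3.40. Aars, the alanyl-tRNA synthetase gene, rose by 2.48 there.

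Other lists gave these values in the tumour libraries labelled CD71+. Of 16 early neutrophil and primary granule genes 5 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.485), with Cd34 and Sox4 of progenitors rising by 3.56 and 2.15. Of 18 secondary granule genes 2 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.29), and the list passed without tumour CD71− replicate 1 (0.0187). Of 23 amino acid stress and unfolded protein genes 4 rose and 9 fell (4 and 10 adjusted over the list alone; adjusted p = 0.138), and the list passed without tumour CD71− replicate 2 (0.0409). Of 9 lymphocyte genes 6 rose, 9 adjusted over the list alone (median 2.58, adjusted p = 0.0614), and the list passed without culture CD71+ replicate 1 or 2, tumour CD71− replicate 1, or tumour CD71+ replicate 1 or 2 (0.0443, 0.0456, 0.0449, 0.0127 and 0.0249), with DESeq2 size factors (0.0326) and with no filter (0.0402). Of 9 eosinophil, basophil and mast cell genes 2 rose (2 adjusted over the list alone; adjusted p = 0.901), and of 8 megakaryocyte and platelet genes 2 rose and 2 fell (2 and 3 adjusted over the list alone; median −0.72, or −0.16 at bounds; adjusted p = 0.636). Of 13 mitochondrially encoded transcripts 1 rose, 0 adjusted over the list alone (median 0.75, adjusted p = 0.52), and the list passed without tumour CD71− replicate 1 (0.0449). Of 3 erythroid genes tested 2 rose, also when adjusted over the list alone, too few for a list test. Xist stood between 958 and 4758 CPM in the 8 libraries, and genes of the Y chromosome at no more than 1.45 CPM.

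Further lists passed between tumour and culture. In the CD71− fraction 6 of 10 endothelial and stromal genes rose and 1 fell, also when adjusted over the list alone (median 4.02, or 2.70 at bounds; adjusted p = 0.0354; adjusted p = 0.455 with an estimated correlation), but not without culture CD71− replicate 1 or 2 or tumour CD71− replicate 1 (0.0782, 0.0525 and 0.0523) or with a stricter filter (0.0623). Of 24 lipid genes 15 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.00603; adjusted p = 0.574 with an estimated correlation). Of 19 antigen presentation genes 10 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.91, or −0.02 with total counts; adjusted p = 0.00231; adjusted p = 0.544 with an estimated correlation). Of 19 iron genes 10 rose and 3 fell, also when adjusted over the list alone (median 0.77, or −0.16 with total counts; adjusted p = 0.024; adjusted p = 0.24 with an estimated correlation), but not without culture CD71− replicate 1 (0.0549). In the CD71+ fraction 8 of 10 endothelial and stromal genes rose and 2 fell, also when adjusted over the list alone (median 4.20, or 4.01 at bounds; adjusted p = 0.00479; adjusted p = 0.238 with an estimated correlation), and 18 of 20 immediate early and heat shock genes rose, also when adjusted over the list alone (adjusted p = 4.79e-22; adjusted p = 0.10 with an estimated correlation). Of 23 amino acid stress and unfolded protein genes 18 rose and 2 fell there (19 and 2 adjusted over the list alone; adjusted p = 1.78e-08; adjusted p = 0.126 with an estimated correlation). Of 20 NADPH oxidase and phagocytosis genes 14 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.000333; adjusted p = 0.197 with an estimated correlation). Antigen presentation (11 of 19 higher, 4 lower, also when adjusted over the list alone; adjusted p = 0.00421; adjusted p = 0.477 with an estimated correlation) and iron genes (10 of 19 higher, 2 lower; 11 and 2 adjusted over the list alone; adjusted p = 0.00141; adjusted p = 0.10 with an estimated correlation) passed as well.

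Over the 27 lists fry called 14 in the tumour, 10 in culture, 0 for the difference, and 20 and 19 between tumour and culture in CD71− and CD71+, where camera called 13, 12, 10, 16 and 15.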
